A study of Mus musculus with 9 samples.

How the data were processed

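RNA was measured in 9 libraries of NIH 3T3 cells, a mouse fibroblast line, carrying lentiviral short hairpin RNAs. Per the labels, 3 independent cultures carried shControl, a hairpin against red fluorescent protein, 3 carried shCNKSR2_1 and 3 carried shCNKSR2_2, both directed at Cnksr2. Per the labels' protocols, RNA was isolated with the Qiagen miRNeasy kit and libraries were made with the TruSeq Stranded mRNA kit.

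The deposited values are FPKM, fragment counts scaled by transcript length and by the number of mapped fragments, 1 column per library. Per the submitters' processing notes, STAR (version written there as 25.1b), Cufflinks 2.2.1 and mouse build mm9 were used, with neither the role of each program nor the annotation stated. The table held 10340 genes, identified by symbol alone, and each value in it was above 1 FPKM in all 9 libraries. A gene at or below 1 FPKM in any library was therefore out of reach of every test, so genes silenced or switched on across that level were not measured. Cnksr2 was not analysed here. Counts of fragments were not used here, so the depth of each library is unknown and no counting interval is given. The reference annotation was GENCODE vM21 on build GRCm38, used by symbol only, for transcript GC content and for the order of genes along chromosomes. It is a later build than the submitters' one, so no coordinates are printed.

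Values were taken to log2(FPKM + 1). All 9 libraries went into 1 linear model with 3 group means in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with trend=TRUE), which left 6 residual degrees of freedom. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over the 10340 genes within each contrast. A gene was called at an adjusted p under 0.05. A minimum mean of 1 FPKM removed 0 genes. Fold changes on this scale understate the ratio for genes near 1 FPKM. The SE given with a log2 fold change is the moderated one of the fit. SD is that of FPKM over the 3 libraries of a group.

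The contrasts were each hairpin against shControl and shCNKSR2_2 minus shCNKSR2_1. Genes called with both hairpins in the same direction formed the shared response. Since both hairpin contrasts use the same control libraries, the covariance of the fold changes was set beside 100 simulations of unchanged groups sharing their controls, and the overlap was set beside that of independent lists for each direction. For all counts, other splits of the libraries into groups of equal size were refitted.

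Before the data were examined, 31 gene lists were written for pathways and cell types relevant to fibroblasts, to signalling downstream of Ras, to hairpin expression and to the X chromosome. Lists with at least 4 measured members, 26 in all, were tested with camera in limma at a preset inter-gene correlation of 0.01 and adjusted over the lists within a contrast. The same lists were tested with an estimated correlation and with fry. Camera sets a list against the other genes, while fry asks only whether its members changed. Fry called 18 of the 26 lists with shCNKSR2_1, 20 with shCNKSR2_2 and 15 between the hairpins. A fry call alone therefore does not set a list apart from other genes. A list is said to be called where camera at the preset correlation gave an adjusted p under 0.05, unless another test is named. Member counts were made with p adjusted over all genes and with p adjusted over the list alone. They are to be read beside the share of all genes called, 32.8% with shCNKSR2_1, 48.2% with shCNKSR2_2 and 20.5% between the hairpins. The genes to be named were fixed by rule at the same time. They were the 10 shared genes farthest up and the 10 farthest down by the smaller of both changes, the 5 called genes farthest up and down in each contrast, and up to 4 called members of each list described, by mean size of change over both hairpins. Predicted genes were not named. Members named because they went against their list, and genes named for their place on a chromosome, were chosen after their values were seen.

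The procedure was tested on simulated data drawn from normal distributions with each gene's mean and residual spread. Of 50 genes shifted at each size, 94% were called at 1.25-fold and 100% at 1.5-fold, 2-fold and 3-fold in both hairpin contrasts. Of 10111 unchanged genes, 18, 13 and 0 were called in the 3 contrasts. A list shifted by 0.20 on the log2 scale was called, and 0 others of the 26 were. Simulated genes varied independently of each other, so these false calls do not cover genes or lists whose members move together.

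Other settings written down at the same time as the lists were pseudocounts of 0.1 and 0.01, a minimum mean of 5 FPKM, no minimum, no variance trend, median-ratio rescaling, quantile normalization, replicate number as an additive block, fits on only the groups compared, a minimum change of 1.5-fold, and leaving out each library in turn. Others were added after the data were seen. These were the removal of a loess trend on transcript GC content from each library, a block for 3 libraries whose deviations followed GC content, leaving those 3 out, leaving out shCNKSR2_1 replicates 2 and 3, and subtracting from each library the running median of each gene's 20 neighbours on either side along its chromosome. A place on a chromosome was found by symbol for 9857 genes. Stretches of neighbouring genes that moved together were sought on each chromosome as the highest-scoring segment of at least 20 genes, with single values limited to 1 in size, and scored against 200 shuffles of gene places.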

Results

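Messenger RNA levels were measured in NIH 3T3 cells, an immortalised mouse embryonic fibroblast line, after lentiviral delivery of short hairpin RNAs. A pair of hairpins, shCNKSR2_1 and shCNKSR2_2, targeted Cnksr2, an X-linked gene for a scaffold protein of Ras signalling. The control hairpin, shControl, targeted red fluorescent protein, which these cells do not make. Each group held 3 independent cultures, so n = 3 throughout. The study asks about X-linked tumour suppressor genes that escape X inactivation. Cnksr2 itself was not analysed here, so it is unknown how far either hairpin lowered it, and the comparisons are between hairpins, not between levels of Cnksr2. The depth of the libraries is unknown because the values are FPKM. Column sums lay between 437208 and 450776 FPKM, and the 10 most abundant genes took 7.32% to 7.49% of them.

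The groups were separated along the first principal component, which held 67.5% of the variance. Control libraries lay at -16.6, -16.1 and -16.9 on it and shCNKSR2_2 libraries at 13.8, 13.4 and 13.5. Those of shCNKSR2_1 lay between, with replicate 1 at -1.71 and replicates 2 and 3 at 5.98 and 4.63. Replicate 1 of shCNKSR2_1 thus stood apart from its own group, and its effect is given beside the gene groups it decides.

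The first question was which genes changed with both hairpins. Chemokine genes were 5 of the 10 genes farthest down. Cxcl5, a chemokine that attracts neutrophils, went from 489 ± 13.7 FPKM (SD) in controls to 31.2 ± 3.53 with shCNKSR2_1 and 15.5 ± 0.313 with shCNKSR2_2, log2 fold changes of -3.93 and -4.89 (SE 0.06, adjusted p = 2.02e-11 and 2.14e-12). Changes are log2 fold changes, with shCNKSR2_1 first where both hairpins have one. The neutrophil chemokine Cxcl1 fell by 3.35 and 3.92, and the log2 fold changes of the monocyte chemokines were -2.97 and -3.91 for Ccl7 and -2.17 and -2.81 for Ccl2. Cxcl12, a chemokine of stromal cells, fell by 1.68 and 2.72. Decorin (Dcn), a small proteoglycan of the matrix, went from 176 ± 12.3 FPKM to 31.7 ± 7.17 and 22.6 ± 0.298. The death receptor Fas went from 19.8 ± 1.02 FPKM to 3.19 ± 0.413 and 2.15 ± 0.221. Chil1, a secreted chitinase-like protein, Cbr2, a carbonyl reductase, and Enpp2, which makes lysophosphatidic acid, completed the 10 genes farthest down. Enpp2 fell from 7.42 ± 0.480 FPKM to close to the lower limit of the table.

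Mgp, which encodes a matrix protein that inhibits calcification, rose the most. It went from 23.5 ± 0.808 FPKM in controls to 257 ± 36.6 with shCNKSR2_1 and 178 ± 8.51 with shCNKSR2_2, log2 fold changes of 3.39 and 2.87 (SE 0.08, adjusted p = 5.23e-10 and 2.55e-09). The neuropeptide gene Vip rose by 1.93 and 1.61, from 2.31 ± 0.185 FPKM. Pla2g7, which inactivates platelet-activating factor, rose by 1.27 and 1.61, and Inhba, the activin A subunit, by 1.11 and 1.39. The stimulus-induced transcription factor gene Egr3 rose by 1.18 and 1.08, and Atf3, another, went from 1.71 ± 0.157 to 4.48 ± 0.330 and 5.42 ± 0.0694 FPKM. Dusp5, a phosphatase that acts on ERK, rose by 1.02 and 1.13, and Sema3a, a secreted guidance cue, by 1.02 and 1.06. Pi15 and Cgref1 completed the 10 genes farthest up, at 1.19 and 1.12 and at 1.04 and 1.18.

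**Figure D1:**
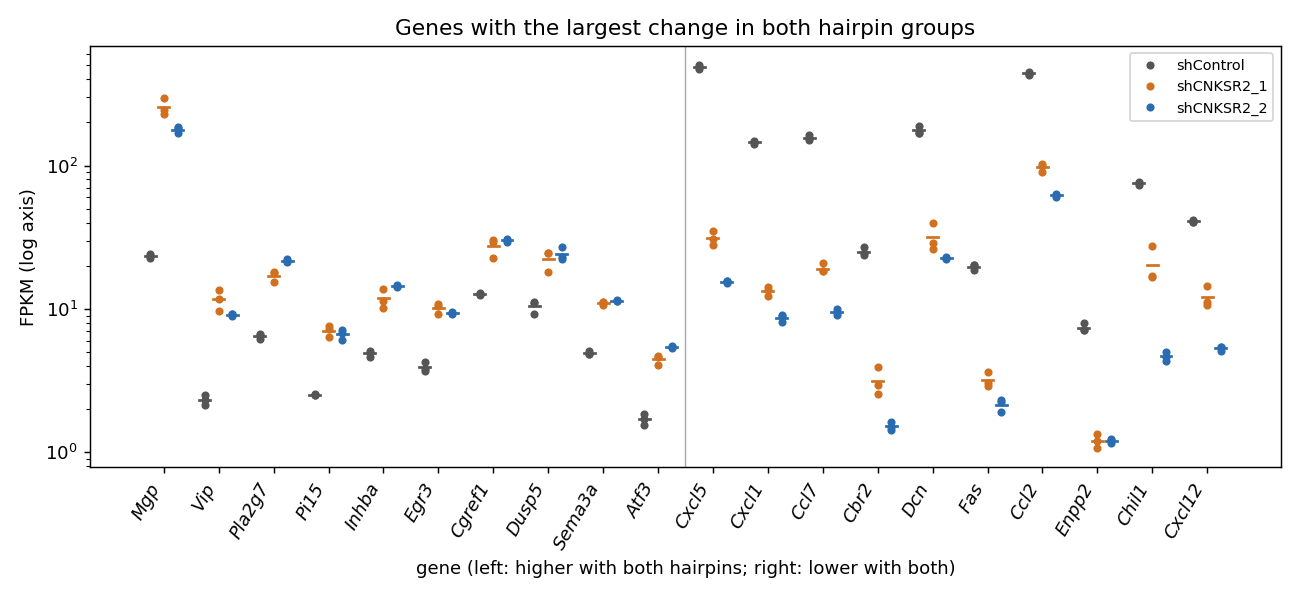
FPKM on a log axis in each of the 9 libraries (points) and group means (bars) for the 10 genes farthest up and the 10 farthest down with both hairpins. Cxcl5 fell from a mean of 489 to 31.2 and 15.5 FPKM, while Mgp rose from 23.5 to 257 and 178 FPKM.

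Of 10340 genes, 2667 (25.8%) changed in the same direction with both hairpins, 1092 higher and 1575 lower. Independent lists would share 281 higher and 562 lower genes. At least a 1.5-fold change in both was seen for 182 of them, 73 higher and 109 lower, and a 2-fold change for 48, 11 higher and 37 lower. Fold changes of both hairpins correlated across genes (Pearson r = 0.827, with genes not independent replicates and controls shared). Over the 2667 shared genes alone, the slope of shCNKSR2_2 on shCNKSR2_1 was 1.22. Simulated unchanged groups sharing their controls gave a median r of 0.524 and a highest r of 0.931, so r alone did not exceed what shared controls give, while the covariance was 0.0539 against a highest simulated value of 0.00678. The excess of lower over higher genes depended on scaling, since median-ratio rescaling gave 1389 higher and 1231 lower shared genes and quantile normalization 1302 and 1219, and removal of the GC trend 1630 and 1446. Without shCNKSR2_1 replicates 2 and 3 the shared count was 1388.

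**Figure D2:**
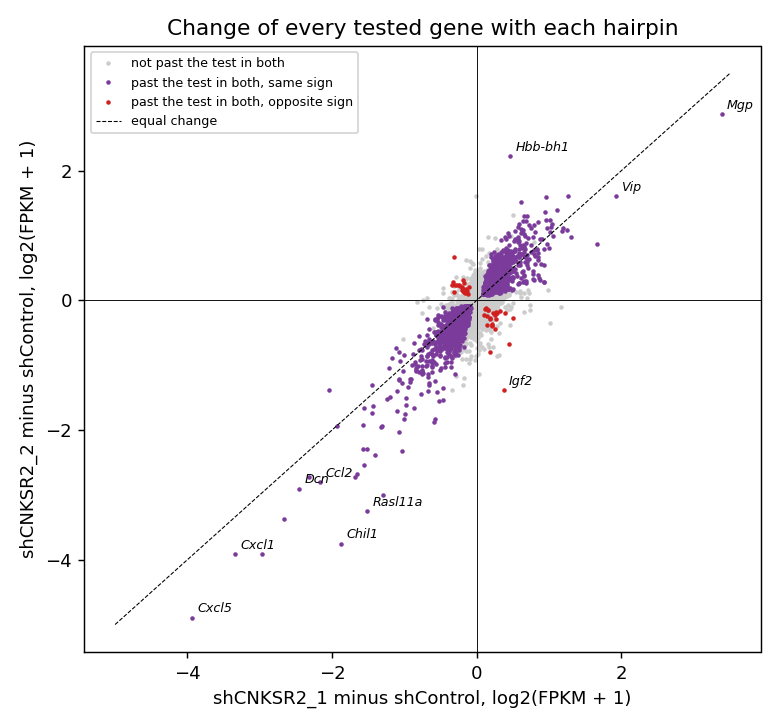
Log2 fold change of each of the 10340 genes with shCNKSR2_2 (vertical) against that with shCNKSR2_1 (horizontal), both relative to shControl. The 2667 genes called in the same direction lie along a slope of 1.22, and 45 were called in opposite directions.

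Among the gene lists, NF-kB and cytokine genes fell with both hairpins. With shCNKSR2_1, 14 of 16 members fell and 2 rose, and with shCNKSR2_2, 13 fell and 2 rose, with the same counts when adjusted over the list alone. The chemokines Cxcl5, Cxcl1, Ccl7 and Ccl2 led the list. The test gave adjusted p = 1.08e-08 and 4.46e-07, and this was the single list still called with an estimated correlation in either contrast (adjusted p = 0.0153 and 0.0242 with an estimated correlation). Nfkbia, the inhibitor of NF-kB that is itself an NF-kB target, fell by 1.21 and 1.05. Both members that rose were Ptgs2, the inducible cyclooxygenase, at 0.96 and 1.24, and Cx3cl1, a membrane-bound chemokine, at 0.80 and 0.31.

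Transcriptional targets of the ERK pathway rose with both hairpins, 14 of 22 with shCNKSR2_1 and 16 with shCNKSR2_2, while 1 fell in each (16 up and 1 down, and 16 up and 3 down, when adjusted over the list alone). Dusp5 went from 10.5 ± 1.06 to 22.4 ± 3.75 and 24.2 ± 2.59 FPKM. The ERK phosphatase Dusp4 went from 11.1 ± 0.342 to 18.3 ± 4.58 and 28.7 ± 0.873 FPKM, and the EGF-receptor ligand Hbegf from 6.88 ± 0.407 to 14.6 ± 2.67 and 16.0 ± 0.331 FPKM. Plaur, the urokinase receptor, rose by 0.75 and 1.12. The member that fell with both was Myc, a driver of growth genes, at -0.15 and -0.28. Adjusted p was 2.80e-08 and 5.43e-06, against adjusted p = 0.128 and 0.365 with an estimated correlation. Over 8 members with clear changes, shCNKSR2_1 replicate 1 lay at 0.442 of the way from control to replicates 2 and 3.

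Immediate early genes, which answer growth factors and stress without new protein synthesis, rose in 12 of 17 cases with shCNKSR2_1 and in 13 with shCNKSR2_2, while 1 and 2 fell (14 and 2, and 13 and 2, when adjusted over the list alone). Beside Egr3 and Atf3, the nuclear receptor genes Nr4a1 and Nr4a2 rose, by 0.93 and 0.55 and by 0.68 and 0.88. Junb, an AP-1 subunit, fell by 0.55 and 0.76, and Ier5 fell by 0.15 with shCNKSR2_2. The list test gave adjusted p = 5.49e-08 and 1.25e-05, and adjusted p = 0.128 and 0.365 with an estimated correlation.

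Genes of the NRF2 antioxidant programme rose with both hairpins, 14 of 23 with shCNKSR2_1 and 18 with shCNKSR2_2, with 1 and 2 falling (15 and 1, and 18 and 2, when adjusted over the list alone). Sqstm1, an autophagy receptor, went from 152 ± 2.68 to 237 ± 24.1 and 322 ± 19.7 FPKM. Heme oxygenase (Hmox1) rose by 0.75 and 0.75, Gclm, of glutathione synthesis, by 0.51 and 0.76, and the peroxidase Prdx1 by 0.48 and 0.76. The metallothionein Mt2 fell by 0.38 and 0.49, and the glutathione transferase Gstm1 fell by 0.25 with shCNKSR2_2. Adjusted p was 5.49e-08 and 4.46e-07, against adjusted p = 0.351 and 0.520 with an estimated correlation. Replicate 1 of shCNKSR2_1 lay at 0.485 of the way from control to replicates 2 and 3 here, against 0.989 for NF-kB and cytokine genes.

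Cholesterol and fatty acid synthesis genes rose in 22 of 26 cases with shCNKSR2_1 and none fell, and in 14 cases with shCNKSR2_2, where Acly, which makes cytosolic acetyl-CoA, fell by 0.30. The counts were the same when adjusted over the list alone. Msmo1, of sterol synthesis, rose by 0.47 and 0.43, from 94.7 ± 3.13 FPKM in controls. Insig1 rose by 0.43 and 0.43 and Fdps by 0.41 and 0.28. The test gave adjusted p = 5.56e-13 and 7.00e-04, and adjusted p = 0.0898 and 0.395 with an estimated correlation. Direct comparison of the hairpins found 0 of 26 members higher and 13 lower with shCNKSR2_2 (0 and 15 when adjusted over the list alone, adjusted p = 2.45e-05, and adjusted p = 0.149 with an estimated correlation).

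Unfolded protein and integrated stress response genes rose in 14 of 27 cases with shCNKSR2_1 and 11 with shCNKSR2_2, while 2 and 3 fell (16 and 2, and 11 and 3, when adjusted over the list alone). The cystine transporter Slc7a11, Nupr1 and the mitochondrial folate enzyme Mthfd2 rose, by 0.29 and 0.58, by 0.38 and 0.43 and by 0.48 and 0.31. The call of Slc7a11 with shCNKSR2_1 was lost without any 1 control library, without replicate 2 or 3 of that hairpin (adjusted p from 0.0519 to 0.0868 over these) and without both replicates (0.05, adjusted p = 0.604). The largest change went the other way, since Cebpb, a transcription factor also active in inflammation, fell by 0.62 and 1.01. Adjusted p was 4.69e-06 and 0.0145 (adjusted p = 0.128 and 0.520 with an estimated correlation), and the shCNKSR2_2 call ended under quantile normalization (0.0585), with a minimum mean of 5 FPKM (0.0638) and with the neighbourhood trend removed (0.0723). Adhesion genes rose in 10 of 19 cases with shCNKSR2_1 and 9 with shCNKSR2_2, and 5 fell in each (11 and 5, and 9 and 5, when adjusted over the list alone). Alcam, Itga8 and Pcdh19 rose by 0.65 and 1.03, by 0.65 and 0.84 and by 0.61 and 0.71. That list was called at adjusted p = 0.00745 and 0.0470 (adjusted p = 0.128 and 0.365 with an estimated correlation). Both calls ended with a minimum mean of 5 FPKM (0.0726 and 0.193). The second also ended under either rescaling (0.0741 and 0.0768), with the GC trend removed (0.0851), without the 3 libraries linked to GC content (0.0717) and without any of 4 single libraries, shControl replicates 1 and 3, shCNKSR2_1 replicate 3 and shCNKSR2_2 replicate 3 (0.0530 to 0.0647).

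**Figure D3:**
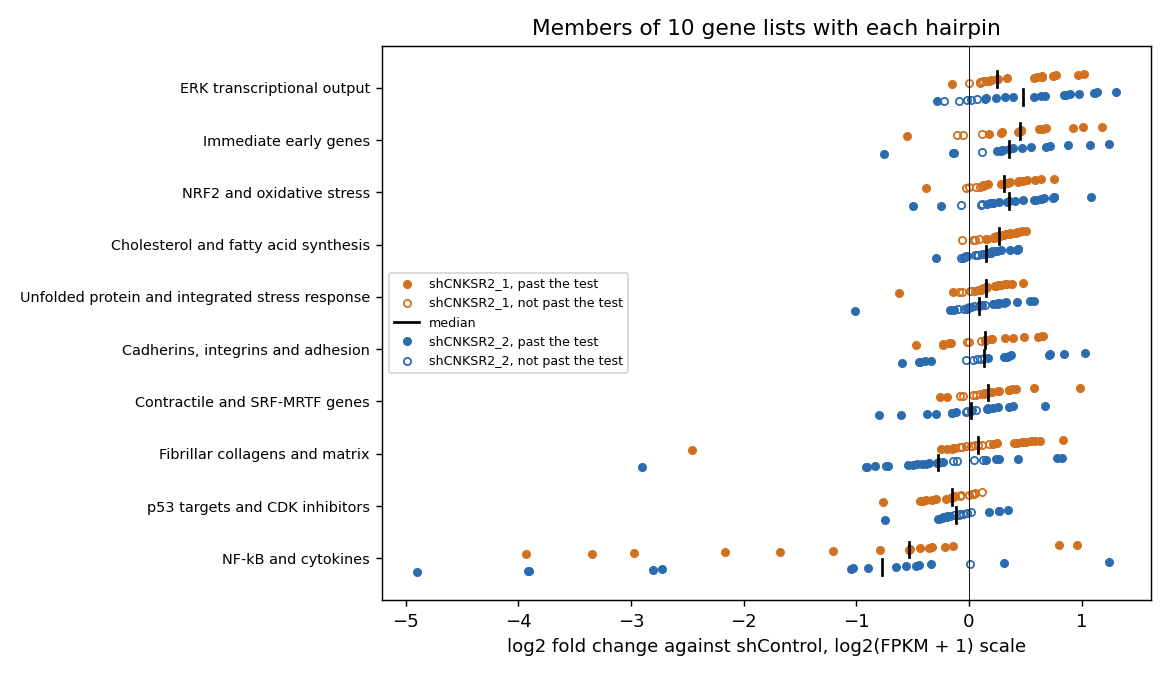
Log2 fold change against shControl of each member (points, filled where the gene passed the test) of 10 gene lists, with the median as a bar, for shCNKSR2_1 and shCNKSR2_2. NF-kB and cytokine genes lie lowest with medians of -0.53 and -0.77, and ERK output genes lie high with medians of 0.25 and 0.48.

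The comparison of shCNKSR2_1 with shControl asked what this hairpin changed. Beside the shared genes, the interferon-inducible gene Ifi27l2a went from 2.87 ± 0.357 to 11.4 ± 2.27 FPKM (1.67 ± 0.12 SE, adjusted p = 3.29e-06), and Gas2, a cytoskeletal regulator, rose by 1.30. The interferon response list did not rise, with 1 of 10 members up and 4 down (camera adjusted p = 0.337). With shCNKSR2_2, 1 rose and 5 fell (camera adjusted p = 0.0899, fry adjusted p = 0.00277). Contractile and SRF-MRTF genes rose in 11 of 20 cases and fell in 2 (12 and 2 when adjusted over the list alone), led by the myosin light chain Myl9 at 0.99 and by Csrp2 at 0.57. Collagens and matrix genes rose in 11 of 27 cases and fell in 4, with the same counts when adjusted over the list alone. The basement membrane collagens Col4a2 and Col4a1 rose by 0.84 and 0.63, while Dcn fell by 2.45. Members of the p53 list fell in 9 of 18 cases and 0 rose (10 and 1 when adjusted over the list alone), with Trp53inp1 at -0.76 and Zmat3 at -0.44. DNA replication genes fell in 6 of 31 cases, with Cdc6 and Pole both at -0.25 (Cdc6 at -0.04, adjusted p = 0.434, with the neighbourhood trend removed), and 0 rose, with the same counts when adjusted over the list alone. The share that fell was near that of all genes, of which 1991 of 10340 fell and 1405 rose. Chondrocyte and osteoblast markers rose in 3 of 5 cases (4 when adjusted over the list alone), with the secreted phosphoprotein Spp1 at 0.85 and the transcription factor Sox9 at 0.33 (0.19, adjusted p = 0.0524, without shCNKSR2_1 replicates 2 and 3).

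With shCNKSR2_1, 3396 genes changed (32.8%), 1405 higher and 1991 lower, of which 231 changed by at least 1.5-fold. Median-ratio rescaling turned the balance to 1794 higher and 1564 lower, and quantile normalization to 1661 and 1615. Without replicates 2 and 3 of this hairpin 1860 genes were called. The list tests gave adjusted p = 9.59e-05 for contractile, 0.00298 for collagen, 0.00464 for p53, 0.0175 for DNA replication and 0.00199 for chondrocyte genes. With an estimated correlation these were adjusted p = 0.128, 0.5997, 0.128, 0.5997 and 0.128. Leaving out shCNKSR2_1 replicate 1, the library that stood apart, ended the collagen call (adjusted p = 0.0877) and the DNA replication call (adjusted p = 0.211).

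The comparison of shCNKSR2_2 with shControl asked the same of the second hairpin. Hbb-bh1, an embryonic globin gene, went from 3.31 ± 0.127 to 19.1 ± 0.907 FPKM (2.22 ± 0.08 SE, adjusted p = 1.13e-08). Prl2c3, one of several nearly identical proliferin genes among which fragments are hard to assign, went from 23.7 ± 5.81 to 76.1 ± 27.0 FPKM. All 4 measured adipocyte markers fell, with the same count when adjusted over the list alone. The fatty acid carrier Fabp4 fell by 1.31, resistin (Retn) by 0.85, the lipase Lpl by 0.68 and Lipe by 0.33. Their test gave adjusted p = 0.00962, and adjusted p = 0.365 with an estimated correlation. With shCNKSR2_1, Fabp4 fell, by 1.44, and the other members did not pass over all genes (2 lower and 1 higher when adjusted over the list alone). Contractile genes went both ways with shCNKSR2_2, 7 up and 7 down of 20, so that their median (0.02) and mean (-0.002) differed in sign. Collagen and matrix genes rose in 6 of 27 cases and fell in 17. The list was not called by camera (adjusted p = 0.0867) but was called lower with fry (adjusted p = 0.0121).

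In all, 4984 genes changed with shCNKSR2_2 (48.2%), 2066 higher and 2918 lower, of which 458 changed by at least 1.5-fold. The balance depended on scaling here too, with 2460 higher and 2424 lower under median-ratio rescaling and 2533 and 2296 under quantile normalization.

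The direct comparison of the hairpins asked where their effects differed. Collagens and matrix genes were lower with shCNKSR2_2 than with shCNKSR2_1 in 21 of 27 cases and higher in 2 (23 and 2 when adjusted over the list alone), the strongest list result of this contrast at adjusted p = 1.38e-12 (adjusted p = 0.149 with an estimated correlation). The collagen cross-linking enzyme Lox averaged 254 ± 4.49 FPKM in controls, 234 ± 56.5 with shCNKSR2_1 and 136 ± 7.24 with shCNKSR2_2, and Dcn was lower by a further 0.45 with the second hairpin, a call lost without any 1 shCNKSR2_2 library (adjusted p from 0.0515 to 0.0638). Without shCNKSR2_1 replicate 1 that difference of Dcn was -0.28. Contractile genes were lower in 11 of 20 cases and higher in 0 (11 and 1 when adjusted over the list alone), at adjusted p = 1.83e-04 and adjusted p = 0.149 with an estimated correlation. Myl9 lay at -0.82 and Tpm1 at -0.35. Igf2, a fetal growth factor, rose with shCNKSR2_1 and fell with shCNKSR2_2, at 9.56 ± 0.439, 12.9 ± 3.06 and 3.04 ± 0.0525 FPKM (difference -1.76 ± 0.11 SE, adjusted p = 1.50e-05). The first of these changes had adjusted p = 0.0280 and was lost when any 1 control library was left out (0.0566 to 0.0881). Without shCNKSR2_1 replicate 1 it was 0.20. Upp1, a uridine phosphorylase, did the reverse, at 5.16 ± 0.125, 3.99 ± 0.873 and 8.80 ± 0.320 FPKM, and its fall with shCNKSR2_1 (adjusted p = 0.0299) was also lost when any 1 control library was left out (0.0605 to 0.0842), without shCNKSR2_1 replicate 3 (0.0565) and under quantile normalization (0.0688). Without shCNKSR2_1 replicate 1 its change was -0.18, against -0.32 with it. Chil1, the small GTPase gene Rasl11a and the matricellular gene Wisp2 fell with both and were lower with shCNKSR2_2 by a further 1.88, 1.73 and 1.72. The binding protein gene Igfbp4 was higher by 1.02 with shCNKSR2_1, with a wide spread (6.30 ± 2.94 FPKM), and lower by 1.38 with shCNKSR2_2 than with shCNKSR2_1. Ngef and Nppb, the natriuretic peptide B gene, were higher with shCNKSR2_2 by 0.91 and 0.82.

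Other lists differed between hairpins too. DNA replication genes were higher with shCNKSR2_2 than with shCNKSR2_1 in 9 of 31 cases and lower in 0 (12 and 0 when adjusted over the list alone). The test gave adjusted p = 5.48e-05, and adjusted p = 0.263 with an estimated correlation. The p53 list was higher in 7 of 18 cases and lower in 1 (9 and 2 when adjusted over the list alone), with Zmat3 at 0.21, and the NRF2 list in 7 of 23 and 2 (10 and 2), with Sqstm1 at 0.44. Both had adjusted p = 0.0187, against adjusted p = 0.149 and 0.618 with an estimated correlation, and the NRF2 call ended without shCNKSR2_1 replicate 1 (0.180) or shCNKSR2_2 replicate 1 (0.111) and with fry (0.286). NF-kB and cytokine genes were lower with shCNKSR2_2 in 9 of 16 cases and higher in 2 (9 and 4 when adjusted over the list alone), at adjusted p = 3.15e-04 and adjusted p = 0.132 with an estimated correlation. Growth factor receptors and ligands were lower in 13 of 25 cases and higher in 5 (13 and 6), with Igfbp7 at -0.51 and Fgf7 at -0.36. Matrix proteases were lower in 7 of 16 cases and higher in 3 (7 and 3), with Mmp19 at -0.50 and Plau at -0.46. These last lists had adjusted p = 0.0166 and 0.00698, and adjusted p = 0.149 and 0.149 with an estimated correlation. A minimum mean of 5 FPKM ended the calls of the p53 (0.0990), NRF2 (0.0505) and protease (0.129) lists, and leaving out shCNKSR2_1 replicates 2 and 3 ended that of the receptor list (0.0904).

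Interferon response genes were lower with shCNKSR2_2 than with shCNKSR2_1 in 6 of 10 cases and higher in 1, with the same counts when adjusted over the list alone. Gbp2 and Ddx58 lay at -0.40 and -0.39, the call of Gbp2 being lost without shCNKSR2_2 replicate 3 (0.0605). Adjusted p was 0.0248, and adjusted p = 0.436 with an estimated correlation, and the call ended with a minimum mean of 5 FPKM (0.489), without shCNKSR2_1 replicate 1 (0.0711) and without shCNKSR2_2 replicate 1 (0.05185). Oxidative phosphorylation genes were lower in 8 of 33 cases and higher in 1 (9 and 1 when adjusted over the list alone), with Ndufv2 at -0.16 and Atp5g1 at -0.23 (adjusted p = 0.00593, and adjusted p = 0.271 with an estimated correlation). That list call ended without shCNKSR2_1 replicates 2 and 3 (0.137). The difference of Ndufv2 was lost without shCNKSR2_1 replicate 1 or 3 or shCNKSR2_2 replicate 2 or 3 (0.0578 to 0.112), and that of Atp5g1 without shCNKSR2_1 replicate 3 or shCNKSR2_2 replicate 2 or 3 (0.0829 to 0.105) or shCNKSR2_1 replicates 2 and 3 (0.131). Wnt pathway genes were lower in 5 of 12 cases and higher in 1 (5 and 1), with Wisp2 at -1.72, Wisp1 at -0.47 and Dkk3 at -0.64. They had adjusted p = 0.0187, against adjusted p = 0.149 with an estimated correlation, 0.193 after removal of the GC trend and 0.134 after removal of the neighbourhood trend. Adipocyte markers were lower in 3 of 4 cases (adjusted p = 0.0187, and adjusted p = 0.263 with an estimated correlation), with the same count when adjusted over the list alone. With shCNKSR2_1 against control, where the receptor, protease, oxidative phosphorylation and Wnt lists were not called by camera, the median, mean and test of each differed in sign. There fry called the receptor list lower (adjusted p = 0.00140) and not the others.

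In all, 2121 genes differed (20.5%), 944 higher and 1177 lower with shCNKSR2_2, and 116 by at least 1.5-fold. Quantile normalization gave 1076 higher and 1061 lower, and removal of the GC trend 1509 and 1302. Of the 2667 shared genes, 701 (26.3%) also differed between hairpins, 607 of them farther from control with shCNKSR2_2. Single libraries weighed on the count of 2121, which was 1208 without shCNKSR2_2 replicate 3, 1231 without its replicate 2 and 1230 without the 3 libraries linked to GC content.

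Several lists were not called by camera in any contrast. Components of the Ras-MAPK cascade went both ways, 1 up and 7 down of 25 with shCNKSR2_1 and 5 and 5 with shCNKSR2_2. Rras lay at -0.61 and -0.86, and Rasa1, a GTPase-activating protein that switches Ras off, at 0.31 and 0.44. Escape genes and homologs of the tumour suppressors under study changed in 2 of 12 cases with each hairpin, against 32.8% and 48.2% of all genes. The changed ones were 1 up and 1 down with the first and 2 down with the second. Of these Mid1 fell by 0.48 and 0.62 and Utp14a rose by 0.15 with the first, a call lost without shControl replicate 2 or 3 or shCNKSR2_1 replicate 2 or 3 (0.0597 to 0.0771) or both of these (0.320). TGF-beta and BMP targets went 4 up and 9 down, then 5 and 11, of 22, with Inhba up and the inhibitor Smad6 at -0.68 and -0.72. Hypoxia and glycolysis genes went 7 up and 5 down, then 9 and 10, of 25, with the vasodilator gene Adm at -1.11 and -1.39. YAP-TEAD targets went 2 up and 4 down, then 5 and 5, of 13, with Ctgf at 0.42 and 0.63 and Amotl2 at -0.55 and -0.53. Genes for the microRNA machinery went 0 up and 6 down, then 1 and 6, of 12, with Tnrc6b at -0.24 and -0.23. Adjusted p of camera for these 6 lists lay between 0.143 and 0.976 with the hairpins against control. With fry, which does not compare a list with other genes, 3 of them were called lower with both hairpins. These were Ras-MAPK (adjusted p = 0.00356 and 0.00484), TGF-beta (0.00689 and 0.00309) and microRNA genes (3.93e-04 and 6.63e-04). Between hairpins, fry called the hypoxia list lower with shCNKSR2_2 (adjusted p = 0.0215). When adjusted over the list alone, the counts were the same for the Ras-MAPK, hypoxia and microRNA lists, 5 and 10, then 6 and 12, for TGF-beta, 3 and 6, then 5 and 5, for YAP-TEAD, and 1 and 1, then 0 and 1, for escape genes. Median, mean and test differed in sign for Ras-MAPK, YAP-TEAD and escape genes with shCNKSR2_2 and for hypoxia genes with shCNKSR2_1. Markers of other cell types were sparse, since 1 endothelial, 2 macrophage and 3 neural markers were measured and no skeletal muscle or epithelial marker was. The endothelial gene Egfl7 rose by 0.25 with shCNKSR2_1 (a call lost without shControl replicate 1 or 2 or shCNKSR2_1 replicate 1 or 3, 0.0564 to 0.0839), the neuronal tubulin Tubb3 rose by 0.34 (0.10, adjusted p = 0.354, without shCNKSR2_1 replicates 2 and 3) and 0.74, and with shCNKSR2_2 Map2 rose by 0.63 and Dlg4 fell by 0.18. Neither macrophage marker, Cd68 nor Cd14, passed over all genes, and 1 was higher with shCNKSR2_1 when adjusted over the list alone.

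Most genes in 1 stretch of chromosome 11 were lower with both hairpins relative to all genes, a feature sought only after the data were seen. From Luc7l3 to Cant1, 247 of the 812 measured genes of that chromosome had median log2 fold changes of -0.18 and -0.21 relative to all genes, and 87.4% and 86.6% of them lay below the median of all genes. The rest of the chromosome lay at 0.02 and 0.05. With shCNKSR2_1, 165 genes of the stretch fell and 8 rose, and with shCNKSR2_2, 182 fell and 14 rose. It held 154 of the 1575 genes lower with both hairpins. The mitotic genes Birc5 and Top2a lay in it and fell by 0.41 and 0.51 and by 0.26 and 0.43, as did the ribosomal protein genes Rpl19 and Rpl27, which fell by 0.20 and 0.23 and by 0.12 and 0.18. The lists they belong to were not called by camera. Mitotic genes went 1 up and 9 down, then 2 and 14, of 30 (camera adjusted p = 0.3401 and 0.0880), and ribosomal proteins 0 and 3, then 2 and 7, of 35 (camera adjusted p = 0.862 and 0.439). With fry, the mitotic list was called lower with both hairpins (adjusted p = 0.0112 and 9.53e-04) and with shCNKSR2_2 against shCNKSR2_1 (0.0389). Adjusted over the list alone, the mitotic counts were the same and the ribosomal ones 0 and 1, then 2 and 5, and ribosomal median, mean and test differed in sign with shCNKSR2_1. Cdc6 and Tnrc6c also lay in the stretch, as did Sox9 and Igfbp4, which went the other way with shCNKSR2_1. With the neighbourhood trend removed, the changes of Rpl19 (0.02 and 0.04), Rpl27 (0.01 with shCNKSR2_1) and Cdc6 (0.08 with shCNKSR2_2) turned positive. The calls of Top2a with shCNKSR2_1 (-0.06, adjusted p = 0.420), Rpl27 (-0.02, adjusted p = 0.590) and Atp5g1 (-0.01, adjusted p = 0.875) with shCNKSR2_2, and Tnrc6c with both (-0.09 and -0.07, adjusted p = 0.0692 and 0.122), were lost. Rpl27 with shCNKSR2_1 was also lost without shControl replicate 1 (0.0593). The stretch is the overlap of the highest-scoring segments, 248 genes from Luc7l3 to Cbx2 with shCNKSR2_1 and 248 from Tob1 to Cant1 with shCNKSR2_2. Shuffled gene places gave no segment scoring as high as these (permutation p = 0.00498 with each hairpin, the smallest that 200 shuffles can give).

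**Figure D4:**
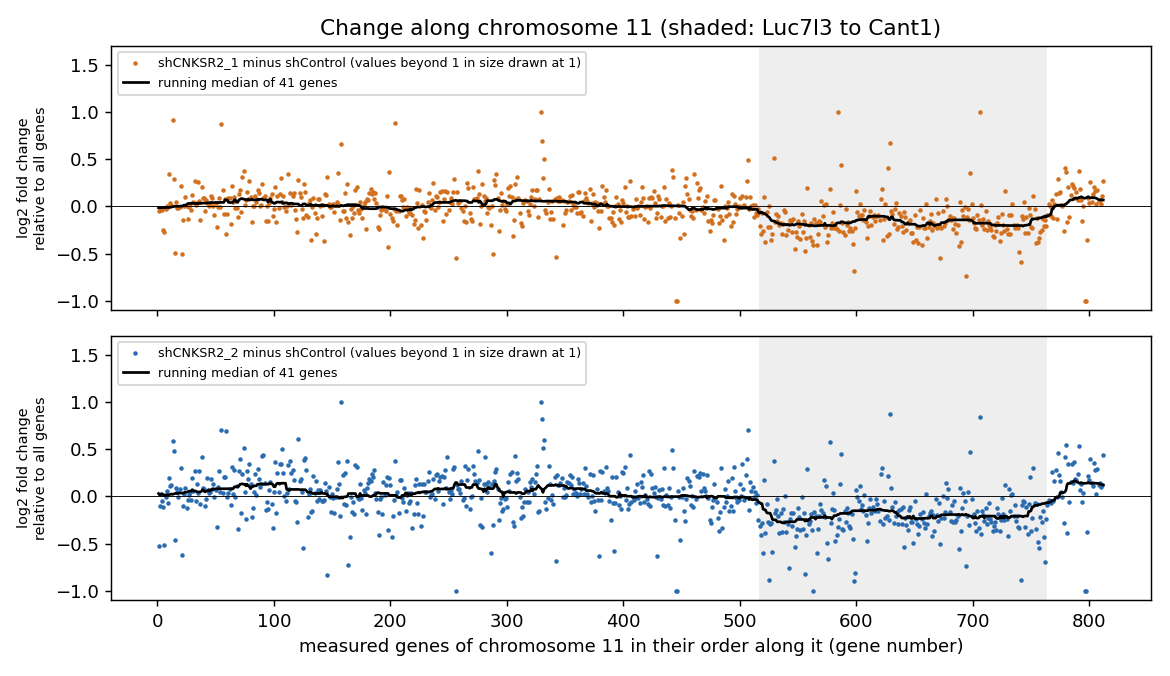
Log2 fold change relative to all genes (points, with values beyond 1 in size drawn at 1) and its running median along the 812 measured genes of chromosome 11, for shCNKSR2_1 (top) and shCNKSR2_2 (bottom) against shControl. In the shaded stretch from Luc7l3 to Cant1 the medians were -0.18 and -0.21, against 0.02 and 0.05 in the rest of the chromosome.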

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

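The tests that weigh explanations here, on splits of the libraries, shared controls, gene places, GC content, copy number, mixing and the control cultures, had their criteria set only after the results were seen.

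A difference between the effects of both hairpins singled out 4 results. Of the genes called with each hairpin, 45 were called in opposite directions, 24 of them higher with shCNKSR2_1 and lower with shCNKSR2_2. Igf2 (0.37, or 0.20 without shCNKSR2_1 replicate 1, and -1.38), Acta2 (0.18 and -0.80) and Col12a1 (0.51 and -0.27) were among them, Acta2 and Col12a1 being named after their values were seen. The median of DNA replication genes was higher by 0.0862 with shCNKSR2_2 than with shCNKSR2_1 (adjusted p = 5.48e-05 for the difference). The median of collagens and matrix genes differed by -0.42 (adjusted p = 1.38e-12). That of Wnt pathway genes differed by -0.13 (adjusted p = 0.0187). Each of these 3 list tests was lost with an estimated correlation (adjusted p = 0.263, 0.149 and 0.149).

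Chance as the source of the separate counts was left undecided, since 10 splits of 6 libraries are too few for a share under 0.05. For genes changed with shCNKSR2_1, 1 of 10 splits reached the real count of 3396. The highest other split gave 0 in limma, with 1241 genes at an unadjusted p under 0.05. With shCNKSR2_2, 1 of 10 splits reached 4984, and the highest other gave 0 in limma and 384 unadjusted. For the difference, 1 of 10 reached 2121, and the highest other gave 0 in limma and 1136 unadjusted. For lists called, 2 of 10 splits reached the 12 of shCNKSR2_1, the others giving 3 to 12, so this count did not exceed that of every mixed split. For shCNKSR2_2, 1 of 10 reached 8 (others 0 to 7), and for the difference, 1 of 10 reached 13 (others 1 to 9). Camera at the preset correlation thus called lists in mixed splits where 0 genes were called, so a list call is weaker evidence than its adjusted p.

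The first pattern was the shared response of 2667 genes. Of 100 drawn splits of the 9 libraries, 1, the real one, reached this count, and the highest other gave 1544. That split, and another giving 478, took the intact shCNKSR2_2 group as the control. A large shared count thus also arose with a hairpin group as the reference. Splits that mix the groups widen the spread within groups, so few genes can be called in them. The test therefore shows that the libraries form separate groups, and it cannot exclude chance differences between cultures as the source. Spread within groups, passed on through the shared controls, was argued against as the whole source. The covariance of both hairpins' fold changes was 0.0539 and the highest of 100 simulations 0.00678. Still, r (0.827) lay below the highest simulated one (0.931), and part of the covariance could come from the shared controls. The simulations were drawn from spread within groups, so they cannot address a control group that differs as a whole. Copy number differences over neighbouring genes as the whole cause were argued against too, since 2451 shared genes were found after the neighbourhood trend was removed, 1963 of them among the 2667. A change of the control cultures alone cannot be told apart from an effect of Cnksr2 loss, because 1 control hairpin was used and 26.3% of the shared genes also differed between the hairpins, and targets shared by both hairpins by accident stay open as untested.

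The second pattern was the stretch of chromosome 11. Chance placing of changed genes was argued against by a permutation p of 0.00498 for the segment of each hairpin, of which the stretch is the overlap. A GC content bias was argued against by a median of -0.18 for the hairpin nearer 0 after removal of the GC trend. A copy number difference between the control and hairpin cultures is a candidate explanation, since 86.6% or more of the genes lay below the median of all genes with each hairpin, highly and weakly expressed genes alike (-0.19 and -0.17, then -0.20 and -0.23). Centred on each gene's mean, the stretch lay at 0.12, 0.11 and 0.15 in the control cultures and between -0.09 and -0.03 in the 6 hairpin cultures. Whether such a difference arose in the control cultures or in both hairpin groups, or whether regulation of the region accounts for it, stays open, since DNA was not measured.

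The third pattern was that shCNKSR2_1 replicate 1 lay apart from replicates 2 and 3. Control RNA or cells in that library alone would give all lists 1 position between control (0) and replicates 2 and 3 (1). Lists took different positions, with medians of 0.442 for ERK output and 0.989 for NF-kB genes (permutation p = 0.00030). The permutation treats genes as independent and replicate 1 is a single library. Such admixture together with variation between cultures can therefore not be excluded. RNA or cells of shCNKSR2_2 in replicates 2 and 3 cannot be told apart from a difference between cultures. Lists took different positions there too, from 0.307 for NF-kB genes to 0.632 for ERK output (permutation p = 0.0036), but replicate 1 as an end point was a single library. A weaker knockdown in replicate 1 stays open as 1 possible biological explanation, untested here, where Cnksr2 was not analysed. Over 344 genes clearly changed in replicates 2 and 3, the position of replicate 1 had a median of 0.758 and an upper quartile of 0.952. Igf2 (16.4 against 10.7 and 11.5 FPKM) and Upp1 (3.09 against 4.84 and 4.05 FPKM) lay farther from control in replicate 1 than in replicates 2 and 3.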

How the results depend on the processing

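Tests on GC content, on gene places and without shCNKSR2_1 replicates 2 and 3 were chosen only after the data were seen. Over 22 settings, 6526 of 6815 values of named genes kept their direction and side of the threshold, 283 were weaker and 6 reversed. Of 790 list values, 731 kept both and 59 were weaker. Of 313 calls of named genes, 75 were weaker or reversed in at least 1 setting. The setting with no minimum could change nothing, since the minimum removed 0 genes. The reversals came with the neighbourhood trend removed, for Rpl19 (0.0243 and 0.0412), Rpl27 (0.0139 with shCNKSR2_1), Rpl4 (0.0119 and 0.0061) and Cdc6 (0.07996 with shCNKSR2_2). A minimum of 1.5-fold cut the counts to 231, 458, 182 shared and 116 for the difference by construction. Without shCNKSR2_1 replicates 2 and 3, the counts were 1860 and 1388 shared and r was 0.638, with 1 library left that was assumed to vary like the others. Named changes with shCNKSR2_1 that moved by over 1.5 times there but stayed called included those of Dusp4 (0.23), Plaur (0.37), Hmox1 (0.37), Gclm (0.32), Cebpb (-0.32), Nupr1 (0.23), Mthfd2 (0.31), Rras (-0.32), Igfbp4 (1.64), Igf2 (0.72) and Upp1 (-0.59), and the differences between hairpins that did so included those of Dcn (-0.79), Mmp19 (-0.83), Ddx58 (-0.59) and Gbp2 (-0.65). Without the 3 GC-linked libraries, the difference fell to 1230 genes and r to 0.8003, with fewer libraries. With its fewer libraries, that setting also ended the calls with shCNKSR2_1 of Dusp4 (0.58, adjusted p = 0.0803), Cebpb (-0.56, 0.0631), Tubb3 (0.27, 0.0939), Igf2 (0.45, 0.0975), Upp1 (-0.34, 0.143), Slc7a11 (0.28, 0.168), Utp14a (0.11, 0.142) and Egfl7 (0.25, 0.0930). Between hairpins it ended those of Nppb (0.80, 0.0791), Mmp19 (-0.56, 0.0664), Ddx58 (-0.39, 0.0661), Gbp2 (-0.46, 0.0596) and Ndufv2 (-0.19, 0.0531). Lists called with an estimated correlation were 1, 1 and 0, fry called 20 with shCNKSR2_2, and a minimum mean of 5 FPKM left 5 there, with fewer genes. The cause was not tested. Leaving out 1 library gave 2504 to 3894 genes with shCNKSR2_1, 4075 to 5355 with shCNKSR2_2, 1997 to 3158 shared, 1208 to 2333 for the difference, r of 0.773 to 0.867, and 10 to 12, 7 to 9 and 12 to 15 lists. The lowest differences came without shCNKSR2_2 replicate 3 (1208) and replicate 2 (1231). Replicate numbers did not pair the cultures (r of same-number residuals from -0.319 to 0.428), and a block for them gave 3205, 4827, 2511 and 1944 genes. Depth was unknown, so what it limits was not assessed.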

Other observations

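The families by gene symbol and the tests on GC-linked libraries and on other chromosomes were chosen only after the data were seen.

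Proteasome genes rose with both hairpins. Of 14 Psmd genes, for the regulatory particle, 9 rose and 1 fell with shCNKSR2_1, and 10 rose and 1 fell with shCNKSR2_2, at medians of 0.16 and 0.22 (adjusted p = 0.0128 and 0.00367 over 152 families of at least 8 members, and adjusted p = 0.944 and 0.963 with an estimated correlation). Of 8 Psmb genes, for the catalytic core, 5 and 7 rose and 0 fell, at medians of 0.17 and 0.24 (adjusted p = 0.0261 and 0.0389, and adjusted p = 0.944 and 0.963 with an estimated correlation). Annexin genes, for calcium-dependent membrane binding proteins, rose in 5 of 8 cases with shCNKSR2_1, where 2 fell, and in 6 with shCNKSR2_2 (adjusted p = 0.0237 and 0.0105, and adjusted p = 0.944 and 0.963 with an estimated correlation). Zinc finger genes of the Zfp family fell in 67 of 275 cases with shCNKSR2_1 and rose in 5, at a median of -0.09 (adjusted p = 0.0128, and adjusted p = 0.944 with an estimated correlation). Over all genes, 1991 of 10340 fell and 1405 rose with this hairpin.

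Between the hairpins, Col genes were lower with shCNKSR2_2 in 12 of 18 cases and higher in 2, at a median of -0.22 (adjusted p = 0.000979, and adjusted p = 0.942 with an estimated correlation). Families of respiratory complex I, Ndufa and Ndufb, were lower in 5 of 13 and 4 of 10 cases, and Fkbp genes, many of them prolyl isomerases of the secretory pathway, in 5 of 13 (adjusted p = 0.0247 for each, and adjusted p = 0.942 for each with an estimated correlation). The Col family shares members with the collagen and matrix list, and the Ndufa and Ndufb families with the oxidative phosphorylation list. They are therefore not separate evidence from those lists.

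Along other chromosomes, the highest-scoring segment of the difference between hairpins covered 547 of the 559 measured genes of chromosome 1, from Cops5 to Cd34. This was nearly the whole chromosome and not a local stretch (permutation p = 0.00498 with gene places shuffled). It lay at -0.07 relative to all genes, with 77.5% of its genes below the median, 20 higher and 150 lower with shCNKSR2_2. Median changes relative to all genes were -0.07 and -0.07 on chromosome 9 and 0.04 and 0.09 on chromosome 10.

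Within groups, shControl replicate 3, shCNKSR2_1 replicate 3 and shCNKSR2_2 replicate 1 deviated from their group means together (r = 0.428, 0.445 and 0.393 across genes). Their deviations followed transcript GC content, with Spearman coefficients of 0.718, 0.544 and 0.561 across genes. These libraries fall 1 in each group. A block for them gave 4345, 5779 and 3356 shared genes and 2988 for the difference.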
